A study of Homo sapiens with 2 samples.

How the data were processed

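ChIP-seq with an antibody against TCF19 was analysed in Ishikawa cells infected with a control or a TCF19-overexpressing lentivirus and selected with puromycin, per the labels' protocols. Cells were fixed in formaldehyde and chromatin was sheared with a Bioruptor sonicator, per the labels' protocols. Reads were aligned to hg38 with BWA 0.7.12 and peaks were called with MACS2 2.1.0, per the submitters' processing notes. The parameters of alignment and peak calling, the handling of duplicate reads and the use of an input library are not given in the sources used here. Each of the 2 libraries had its own peak list, so peaks were called per library. Groups were taken from the genotype label, and each group had 1 library.

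The files hold, per summit, the interval, a score, a fold enrichment, a −log10 p-value, a −log10 q-value and the position of the summit within the interval. The deposited score was the whole-number part of the −log10 q-value times 10 at 99.998% of control summits and at 100% of overexpression summits. The fold enrichment (a ratio of summit pileup to local background) is the authors' value, and it was used only to describe, rank or filter peaks within its own list. The deposited −log10 q-values start at 1.3011 in both lists, which corresponds to a q-value of 0.05, and the deposited −log10 p-values were used to recover pileups. The summit position deposited with each peak was counted from the start of the interval, and coordinates are printed from 1 on hg38. Intervals that held several summits were counted once for overlap and by summit for position.

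Summit pileups were recovered in whole reads from the deposited fold and −log10 p-value. A fold of (pileup + 1) / (background + 1) and a Poisson tail at that background were solved for a whole-number pileup, with a misfit of at most 0.001 in −log10 p. This gave a whole pileup at 99.997% of control and 99.996% of overexpression summits, with 5 and 4 summits not recovered. The same values gave a floor of the background, which is the genome average, at 39.34% of control and 21.13% of overexpression summits. Above the floor the background was a whole number of reads in 10 kb (within 0.05 of a read) at 100% of summits, with fragment lengths of 273 bp in control and 276 bp in the overexpression library. With a fragment length 3 bp shorter or longer, 9.61% to 11.83% were whole. The local background therefore matches reads of the ChIP library itself in 10 kb windows without scaling. The values look like calls made without an input library, so folds and peaks are not to be read as corrected for input. The depth was taken as the genome average, 57.96 and 51.76 reads per 10 kb. Exact Poisson intervals were given for pileups and Wilson intervals for shares, both at 95%, and they cover counting error only, since summits were picked as local maxima and reads may hold PCR copies.

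Analyses used chromosomes 1 to 22 and X, which left out 792 control and 643 overexpression summits on other contigs. Overlap needed at least 1 bp. It was set against 100 seeded placements of the list's own intervals on the same chromosome, with the other list kept in place. It was also set against the list's own intervals moved by 5 to 50 kb. Summits of 41014 pairs within 100 bp of each other were compared by the log2 ratio of pileups, each over its genome average, with 1000 bootstrap draws over peaks. For each interval, the probability that the other library would call an equal occupancy was computed, and 0.95 was the threshold. It used the interval's own pileup and local background, scaled to the other library's depth. The other library's local background at that place was not used. Summits are picked as local maxima, so these probabilities can be too high. Gene positions came from a RefSeq table of GRCh38.p14 with 19974 protein-coding genes. It gives gene spans with no strand and no exons, and no genome sequence was used here. The plan made before the data were examined used transcription start sites. In their place, a window of 1000 bp on each side of both gene ends was used; exons and introns were not separated, and the planned results on sequence at summits were not computed. Random placement of summits on the same chromosome gave the chance level, and it includes assembly gaps and regions where reads cannot be placed.

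The 23 gene lists were fixed before the data were examined and include G1/S, DNA replication, mitosis, PI3K and FOXO, MAPK, Wnt, DNA damage response, oestrogen response and endometrium, epithelial, mesenchymal, interferon and inflammation, glucose metabolism, ribosomal proteins, housekeeping, chromatin regulators, histones, and lists of liver, neuron, muscle, blood, epidermis and testis, and olfactory receptor genes. One list gene (LOR) was not found in the gene table and 1 was matched by an older symbol. A list's count was placed among 10000 seeded random lists of as many protein-coding genes, and no p-value was computed, since 1 library per group gives no spread. The genes named were fixed by rule before the data were examined: TCF19 and genes whose promoters are common in lentiviral vectors; the 10 summits of highest fold per library; the 10 genes of highest gene-end fold in both lists, in the overexpression list alone and in the control list alone; and up to 4 members of each gene list per class. Some genes the rule takes, and 1 of the lists, are not reported here. Further list members were named from the class counts, after their values were seen.

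The alternatives tried were stricter q-values, other overlap rules, equal numbers of peaks of highest fold, other windows, all annotated genes, and, added after the data were seen, limits on local background and on depth, gene-length matching of random lists and moved intervals. The steps were tested on simulated data. Pileups were recovered exactly at 100% of 19201 simulated control and 19232 simulated overexpression summits, while pileups scaled by a factor were taken as whole at 0.51% and 0.84%. A planted overlap of 40% of 159748 control intervals came back as 40.01%. Of unchanged lists, 3% exceeded the 95th percentile, and of 200 lists with a planted hit rate of 90%, 99% did. All 200 genes planted with a gene-end summit were found. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.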

Results

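TCF19, a nuclear protein with a PHD finger (a domain that binds histone tails), was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Ishikawa cells, an established human endometrial cancer line. One population carried a control lentivirus and the other a lentivirus that overexpressed TCF19, and the same antibody against TCF19 was used in both. The data were 1 list of called peaks per population, on hg38, so each group had 1 library and no replicate. The question the design addresses is where the antibody enriched DNA and how this differed when TCF19 was overexpressed. No test of the condition was possible; values are given per library, and intervals are 95% intervals that cover counting error only. The control list held 170334 summits and the overexpression list 112212. Read totals were not part of the lists, but the genome average recovered from the peak statistics was 57.96 reads per 10 kb in control and 51.76 in the overexpression library, 0.893 of the control depth.

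The locus of the overexpressed gene differed between the libraries. TCF19 (chromosome 6, 31158589 to 31164215) had 0 called summits in control and 3 in the overexpression library, all inside the gene. The highest stood at 31161734, with a pileup of 143 reads (exact Poisson interval 120.5 to 168.5) and an 11.4-fold enrichment. The others stood at 31159550, with 53 reads (39.7 to 69.3), and at 31162637, with 62 reads (47.5 to 79.5). In the surrounding 100 kb on each side, leaving out the nearest 10 kb, no summit exceeded 23 reads in the overexpression library or 17 in control. The local read density at TCF19 was 423 reads per 10 kb (median of the 3 summits, their own reads included), against a median of 124 at summits in these flanks. The lower end of the neighbouring gene POU5F1 is at 31164337 and the higher end of CCHCR1 at 31158197, and all 3 summits lay between them. The gene table used here has no exons, so the summits were not assigned to exons or introns of TCF19.

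**Figure D1:**
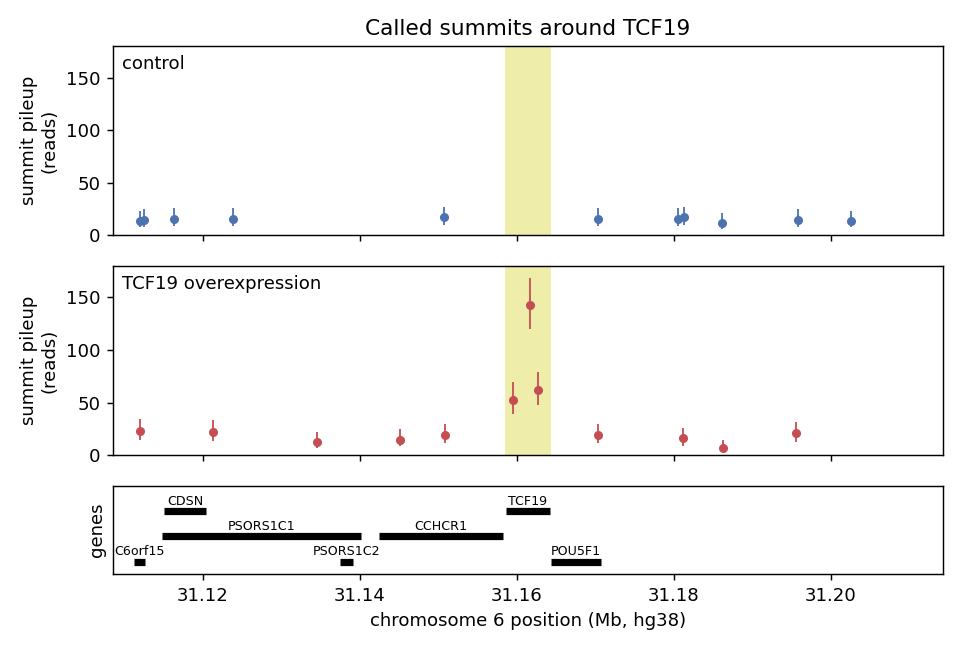
Summit pileup in reads (y axis, bars are exact 95% Poisson intervals) against position on chromosome 6 in Mb (x axis) around TCF19 (shaded) in the control and the overexpression library, with protein-coding genes drawn below. The overexpression library has 3 summits of 53 to 143 reads inside TCF19 and the control has 0.

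EEF1A1 and PGK1, whose promoters are common in lentiviral vectors, had peaks in both libraries. At EEF1A1, which encodes a translation elongation factor, the highest summit had 11 reads (5.5 to 19.7) in control and 21 (13.0 to 32.1) in the overexpression library. PGK1, which encodes a glycolytic kinase, had 14 reads (7.7 to 23.5) and 19 (11.4 to 29.7) at its lower end. The counting intervals of the 2 libraries overlapped at both genes. The local density at EEF1A1 was 1.58 times that of its flanks in the overexpression library and 1.06 times in control. At PGK1 it was 0.94 and 1.14 times.

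The lists were long and their peaks low. On chromosomes 1 to 22 and X, control had 159748 intervals over 73.1 Mb and the overexpression library 101370 over 50.4 Mb, with median widths of 390 and 420 bp. The median summit pileup was 12 reads in control and 13 in the overexpression library, and the 95th percentiles were 20 and 23. The median fold enrichment, the authors' value, was 3.87 in control and 4.05 in the overexpression library, with maxima of 26.1 and 29.3. The number of intervals in the overexpression library relative to control varied by chromosome. The ratio was 0.986 on chromosome 19, 0.884 on chromosome 22 and 0.798 on chromosome 17, against 0.595 on chromosome 3, 0.579 on chromosome 8 and 0.519 on chromosome X.

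Most overexpression peaks had a counterpart in control, and fewer than that share of control peaks had one in the overexpression list. Of the overexpression intervals, 67.36% (Wilson interval 67.07 to 67.65) overlapped a control interval by at least 1 bp, against 5.1% after random placement on the same chromosome. Of the control intervals, 43.01% (42.77 to 43.26) overlapped an overexpression interval, against 3.23% at random. Nearly as many intervals overlapped in each list, 68712 in control and 68286 in the overexpression library. The percentages therefore differ because the lists differ in length. This left 33084 intervals seen in the overexpression list alone and 91036 in the control list alone. In the 70018 overlapping pairs the summits lay a median of 96 bp apart, against 177 bp when summits were redrawn at random within their intervals. Overlap was most frequent at high enrichment: it was 97.2% (94.0 to 98.7) of the 212 overexpression intervals of at least 9-fold and 95.5% (91.6 to 97.6) of the 198 such control intervals. At 3- to 4-fold it was 59.0% (58.5 to 59.6) in the overexpression list and 35.8% (35.4 to 36.1) in control. Depth limits this comparison. An equal occupancy would have been called in the other library with a probability of at least 0.95 for 14.51% of the intervals seen in control alone and 40% of those seen in the overexpression library alone. With both lists cut to their 1000 summits of highest fold, the overlap was 22.86% of control and 22.77% of overexpression intervals. Against the full other list, 87.3% of the 1000 highest control summits and 95.9% of the 1000 highest overexpression summits overlapped an interval.

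**Figure D2:**
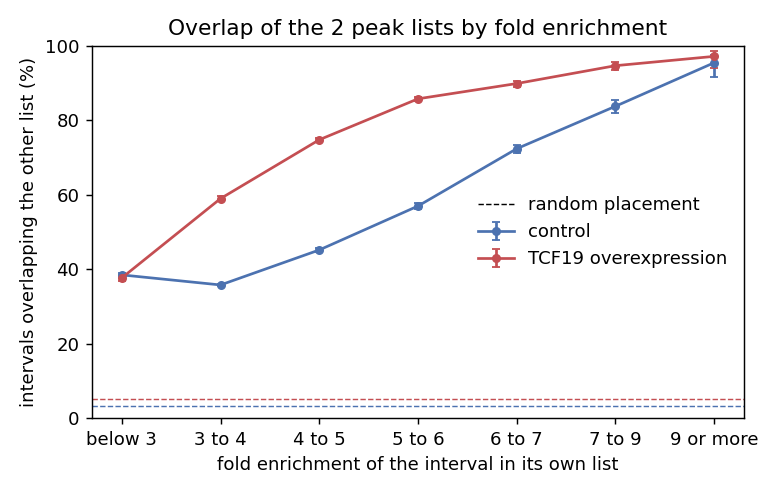
Percent of intervals that overlap the other list (y axis) by fold enrichment in their own list (x axis) for control and overexpression, with 95% Wilson intervals as bars and the level of random placement as dashed lines. Overlap reaches 95.5% of control and 97.2% of overexpression intervals at 9-fold or more, and is 38.5% and 37.7% below 3-fold.

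Summits of the overexpression library lay near ends of protein-coding genes about 1.9 times as often as control summits. Within 1000 bp of either end of a gene lay 15.57% (15.36 to 15.78) of the 111569 overexpression summits and 8.21% (8.08 to 8.34) of the 169542 control summits. Random placement gave 2.61% and 2.47%, so the share was 5.97 times the random level in the overexpression library and 3.32 times in control. Inside genes but farther from the ends lay 41.73% and 44.16% of summits, close to the random 41.06% and 40.82%. Outside genes lay 42.7% and 47.63%, below the random 56.33% and 56.71%. Farther out, 2000 to 5000 bp from a gene end, lay 6.41% of overexpression and 5.85% of control summits. Gene starts and stops were not told apart, because strand was not part of the gene table.

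Intervals seen in 1 list alone differed more. At gene ends lay 13.57% (13.2 to 13.94) of the intervals seen in the overexpression list alone and 2.89% (2.78 to 3.0) of those seen in the control list alone. Among intervals in both lists the shares were 13.4% of overexpression and 13.66% of control intervals. Restricted to intervals the other library had the depth to show, the shares were 15.79% (15.18 to 16.42) of 13232 for overexpression and 2.21% (1.97 to 2.48) of 13209 for control. Gene-end summits made up 11.9% of control summits below 3-fold and 6.24% of those at 5- to 7-fold, while in the overexpression library they made up 17.24% and 16.68%.

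**Figure D3:**
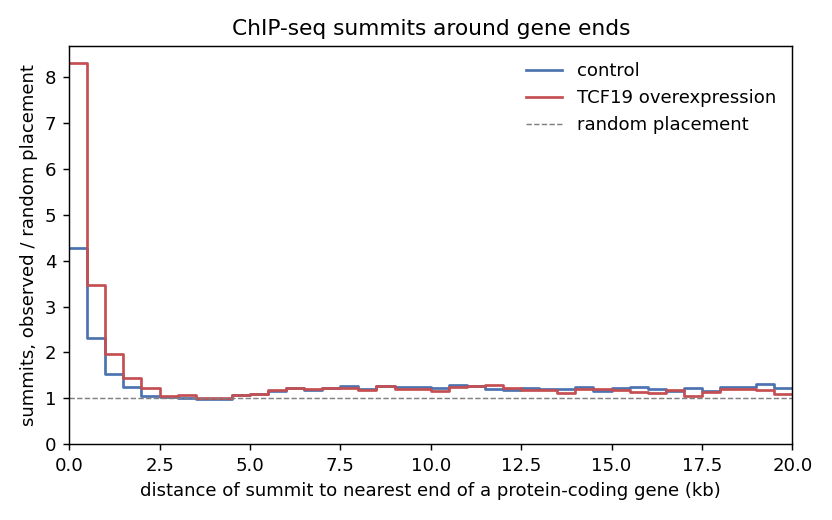
Summits observed over summits placed at random (y axis) by distance to the nearest end of a protein-coding gene in kb (x axis), for control and overexpression, with random placement as the dashed line. In the bin nearest to gene ends the ratio is 8.32 in the overexpression library and 4.27 in control, and the lines meet by about 2.5 kb.

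At paired summits within 100 bp of each other the pileups themselves could be set side by side. At 4684 pairs at gene ends the overexpression pileup, each taken relative to its genome average, exceeded the control pileup by a mean log2 ratio of 0.34 (bootstrap interval over peaks 0.32 to 0.35). At 29307 pairs more than 10 kb from any gene end the mean log2 ratio was 0.07 (0.06 to 0.07). These intervals describe the peaks of 2 libraries and not the spread between cultures.

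Counted by gene, 12935 of 19974 protein-coding genes (64.8%) had a gene-end summit in the overexpression library and 10909 (54.6%) in control. Both libraries had one, at the same end or at different ends, at 9742 genes, where independent lists would share 7064.6. The overexpression library alone had one at 3193 genes, control alone at 1167, and neither at 5872. When the same number of summits of highest fold was taken from each list, the counts were 6302 in both, 6633 in the overexpression library alone and 575 in control alone. In genes longer than 20 kb, where the windows do not meet, both ends had a summit in 6.3% of genes in the overexpression library and 6.5% in control, below the 16.3% and 12.6% of independent ends.

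The genes of highest fold seen in the overexpression library alone included SKA1, which encodes a part of the spindle and kinetochore complex (26 reads, 17.0 to 38.1), and STAMBP, a deubiquitinase gene (22 reads, 13.8 to 33.3). STAMBP had a 9.13-fold enrichment at chromosome 2, 73829089, and SKA1 an 8.79-fold enrichment at chromosome 18, 50375170. Others were STEAP4, a metalloreductase gene, with 19 reads; DTX2 with 21; CHAC2 with 21; TJAP1 with 18; and DROSHA, which encodes the nuclease that starts microRNA processing, with 22. DHFR2 and NSUN3 shared 1 summit of 18 reads at chromosome 3, 94062728, so it cannot be assigned to either.

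The genes of highest fold seen in control alone were led by TYW2, a tRNA modification gene, with 21 reads (13.0 to 32.1) and an 8.52-fold enrichment at chromosome 8, 124451134. RORA, which encodes a nuclear receptor, followed with 19 reads (11.4 to 29.7) and 7.75-fold. PTN (pleiotrophin), MASP1 (a complement protease), LOC128071544 and SLC7A7 (an amino acid transporter) had 18 reads each, and TRIM40 had 17. The chemokine gene CCL4L2 had 27 reads and has near-identical copies, so its place is uncertain. H2AB1 and F8A1, also of families with near-identical copies, shared 1 summit of 16 reads.

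The 10 genes of highest fold in both libraries were mostly members of families with near-identical copies, where reads can be placed on the wrong copy, and they are reported as uncertain. They were GAGE13, GAGE2A, MBD3L3, SLX1A, POTEB2, USP17L22 and FAM90A22, together with CCDC200, LOC101929601 and LOC124900568. CCDC200 had 135 reads (113.2 to 159.8) in control and 132 (110.4 to 156.5) in the overexpression library. GAGE13 had 69 (53.7 to 87.3) and 59 (44.9 to 76.1).

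Genes of cell division were among the groups with the most gene-end peaks in the overexpression library. All 20 mitosis genes had one there, against 14 in control. The 6 seen in the overexpression library alone were AURKB, BUB1, CENPE, CENPF, PLK1 and TTK, which encode mitotic kinases, checkpoint and kinetochore proteins; PLK1 had 23 reads (14.6 to 34.5) and BUB1 19 (11.4 to 29.7). Of 24 DNA replication genes, 22 had a peak against 17 in control, with CDC6, FEN1, MCM10, MCM4 and MCM7 seen in the overexpression library alone. Of 20 genes of the G1/S transition, 17 had a peak against 11, with CCND2, CDK4, CDK6, E2F3, MYC and RBL1 in the overexpression library alone. Pileups differed by gene. POLA1, a DNA polymerase gene, had 17 reads (9.9 to 27.2) in control and 16 (9.1 to 26.0) in the overexpression library, and CDK2 had 20 (12.2 to 30.9) and 22 (13.8 to 33.3). PCNA, the replication clamp, had 17 reads (9.9 to 27.2) in control and 30 (20.2 to 42.8) in the overexpression library. CCNA2 (cyclin A) had 10 (4.8 to 18.4) and 25 (16.2 to 36.9), and CDK1 had 13 (6.9 to 22.2) and 23 (14.6 to 34.5). Within 2000 bp of gene ends the mitosis counts were 20 against 14, and those of G1/S were level, with 18 genes in each library. Among summits whose local background was at most 3 times the genome average, called low local background here, mitosis had 18 against 13, G1/S 10 in each and DNA replication 16 in each. That limit was chosen after the data were seen and is uneven: local background includes the peaks' own reads, and it removed 23.1% of gene-end summits in the overexpression library and 15.8% in control. Counts under it are therefore given as values that decide neither for nor against an excess.

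As a description of these libraries, each count was placed among 10000 random lists of as many protein-coding genes. In the overexpression library, mitosis stood at percentile 99.98, DNA replication at 99.9 and G1/S at 97.34. In control they stood at 91.38, 94.51 and 50.58. Within 2000 bp G1/S stood at 96.34 in the overexpression library and at 99.26 in control. Genes that every cell uses stood as high: 27 of 28 housekeeping genes had a peak in the overexpression library and 19 in control (percentiles 99.99 and 92.1). GUSB, PSMB4, RPLP0, ACTB, TUBB and GPI were among the 9 seen in the overexpression library alone, and ACTG1 was the 1 seen in control alone. Chromatin regulators had a peak at 20 of 22 genes against 16 (percentiles 99.64 and 95.56, or 95.9 and 76.3 among random lists matched on gene length), with HDAC1, KDM4A and SUZ12 among those in the overexpression library alone. KMT2D, a histone methyltransferase gene, had 23 reads (14.6 to 34.5) in control and 51 (38 to 67.1) in the overexpression library. The DNA damage response genes had 18 of 20 against 15 (percentiles 99.24 and 96.65, or 98.08 and 93.08 when matched on gene length), with CHEK2 among those in the overexpression library alone and ATR, FANCD2, CHEK1 and SESN1 among those in both. The FANCD2 summits of highest fold lay at different ends of the gene, at chromosome 3, 10102739 in control and 10026493 in the overexpression library. Housekeeping had 16 genes in each library at low local background (percentiles 73.52 and 86.6), chromatin regulators 12 against 13 (62.21 and 87.92) and the DNA damage response 16 against 13. There, mitosis (percentile 99.98) and the DNA damage response (99.5) were the lists above the 95th percentile in the overexpression library.

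**Figure D4:**
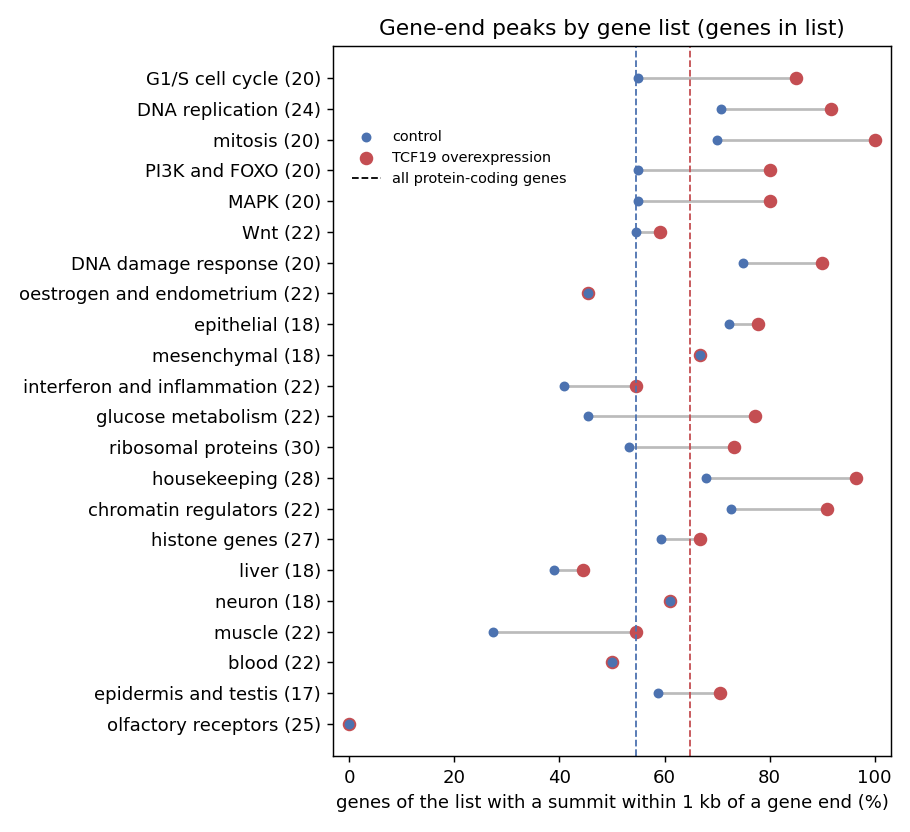
Percent of the genes of each list with a summit within 1 kb of a gene end (x axis) in control (blue) and overexpression (red), with the number of genes of the list in brackets and the level of all protein-coding genes as dashed lines (54.6% and 64.8%). Mitosis reaches 100% in the overexpression library, and the olfactory receptors of the list are at 0% in both libraries.

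Signalling and metabolic groups stood below the 95th percentile of random lists in both libraries within 1000 bp, but within 2000 bp MAPK was above it in the overexpression library (18 of 20 genes against 13, percentiles 96.21 and 48.28). Glucose metabolism had peaks at 17 of 22 genes against 10 (percentiles 88.74 and 19.93). FBP1 and PCK1, which encode gluconeogenic enzymes, and ALDOA, GAPDH, GPI, HK1 and LDHA of glycolysis were seen in the overexpression library alone. PFKM had 19 reads (11.4 to 29.7) in control and 36 (25.2 to 49.8) in the overexpression library. The PI3K and FOXO genes had 16 of 20 against 11 (percentiles 92.34 and 49.86, or 70.13 and 16.12 when matched on gene length), with AKT2, PDPK1, PIK3CB and TSC1 in the overexpression library alone and FOXO3 in control alone. The MAPK genes had 16 of 20 against 11 (92.36 and 51.43), with NRAS, SOS1 and ERBB2 in the overexpression library alone and FOS and MAP2K2 in control alone. Ribosomal protein genes had 22 of 30 against 16 (83.64 and 44.02), but stood at 99.42 and 91.68 among random lists matched on gene length. Interferon and inflammation genes had 12 of 22 against 9 (16.3 and 10.23), with IRF1, NFKBIA and RELA among those in the overexpression library alone and TNFAIP3 in control alone. Wnt genes had 13 of 22 against 12 (29.2 and 48.66), with LEF1, ZNRF3 and GSK3A in the overexpression library alone and AXIN2 and RNF43 in control alone. Histone genes had 18 of 27 against 16 (57.67 and 67.7, or 97.99 and 96.72 when matched on gene length) and are uncertain, since many are near-identical. MAPK had 8 genes against 10 in control at low local background, Wnt 5 against 7, and PI3K and FOXO 11 against 10.

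Groups tied to the tissue of origin had no such excess. Oestrogen response and endometrial genes had peaks at 10 of 22 in both libraries, percentile 3.4 in the overexpression library and 19.83 in control. The low percentile depended on the setting: it was 11.42 and 37.73 among random lists matched on gene length, and 31.81 and 27.78 within 2000 bp, with 15 genes against 13. ESR1, the oestrogen receptor gene, had 11 reads (5.5 to 19.7) in control and 16 (9.1 to 26.0) in the overexpression library. FOXA1, MSX1 and MUC1 were seen in the overexpression library alone, and FOXA2, HOXA9 and PAX8 in control alone. PGR, TFF1, HOXA10 and HOXA11 had none in either. Epithelial genes had 14 of 18 against 13 (86.78 and 93.16); CDH1 had 17 reads (9.9 to 27.2) against 11 (5.5 to 19.7) in control. Mesenchymal genes had 12 of 18 in both (56.06 and 84.01), with VIM in control alone and PDGFRB in the overexpression library alone. There were 6 against 7 epithelial and 8 against 11 mesenchymal genes at low local background.

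Genes of other cell types had fewer gene-end peaks. The 6 lists of liver, neuron, muscle, blood, epidermis and testis, and olfactory receptor genes together had peaks at 44.3% of 122 genes in the overexpression library and 36.9% in control, 7.4 percentage points apart. The 16 lists described before them had 77.1% and 59.9%, 17.2 points apart. At low local background the lists of other cell types had 32.0% and 23.8%, 8.2 points apart, and the 16 lists 52.8% and 50.6%, 2.3 points apart. Liver genes had 8 of 18 against 7 in control (percentiles 4.16 and 9.46, or 11.08 and 25.03 when matched on gene length). Neuronal genes had 11 of 18 in both (37.05 and 69.7, or 22.45 and 55.53 when matched). Blood genes had 11 of 22 in both (7.54 and 34.1, or 22.76 and 58.76 when matched). Muscle genes had 12 of 22 against 6 (15.98 and 0.46, or 20.62 and 0.72 when matched), with CKM, MYH7, MYH8, TNNI1, TNNT1 and TNNT2 in the overexpression library alone. Epidermal and testis genes had 12 of 17 against 10 (67.68 and 62.97, or 88.0 and 83.53 when matched). None of the 25 olfactory receptor genes of the list had a peak in either library, which lowered the joint shares. Epidermal and testis genes (70.6% and 58.8%) lay above the level of all protein-coding genes (64.8% and 54.6%). Neuronal genes (61.1% in both) lay above it in control.

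In all, 6 of the 23 lists stood above the 95th percentile in the overexpression library and 2 in control, where 1.2 are expected of random lists. Ranked by the difference between the libraries, 5 stood above the 95th percentile of random lists: glucose metabolism (98.21), housekeeping (97.98), mitosis (97.02), G1/S (96.94) and muscle (95.62). Most of these depended on the setting. Within 2000 bp, mitosis (98.38) stayed above it, glucose metabolism (74.66), housekeeping (65.24), G1/S (22.91) and muscle (94.02) did not, and MAPK (95.49) and PI3K and FOXO (95.2) passed it. At low local background mitosis (98.15) and muscle (99.18) were above it, and glucose metabolism stood at 93.32, G1/S at 31.53 and housekeeping at 28.28. Over all protein-coding genes the share with a gene-end summit was then 51.1% in the overexpression library and 46.5% in control.

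The peaks of highest fold lay at the same positions in both libraries and mostly far from genes. The highest of all stood on chromosome 6 at 59163229 in control (26.1-fold, 87 reads, 69.7 to 107.3) and at 59163231 in the overexpression library (29.3-fold, 155 reads, 131.6 to 181.4), with PRIM2 the nearest protein-coding gene, 1516.4 kb away. On chromosome 17, the summits at 23016383, 24421468, 25920223 and 26594888 of the overexpression library had 146, 92, 89 and 123 reads, against 71, 55, 57 and 79 at the matching control summits, nearest to KCNJ18 or WSB1 and 699.2 to 2716.9 kb from them. The others near named genes lay 39.5 kb from ZFP14 on chromosome 19 (131 reads in control and 142 in the overexpression library) and 15.4 kb from CCDC200 on chromosome 17 (143 and 161 reads). Further ones lay nearest to EMB on chromosome 5 (69 and 125 reads, 765.2 kb) and, by rank, to LOC102723475 on chromosome 21 and PROS1 on chromosome 3 in control and DCUN1D4 on chromosome 4 in the overexpression library. All 10 highest summits of each library overlapped an interval of the other, and 99 of the 100 highest did so in each. The 10 highest lay a median of 732.2 kb from a gene end in control and 1234.3 kb in the overexpression library, against 32.7 and 22.2 kb over all summits.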

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

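The tests of depth, local background, open DNA, lentiviral copies, alignment and repeats in this part were chosen only after the results were seen; the test of gene-dense regions was written before its result was seen.

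A signal outside the main measurement stood out on the mitochondrial genome, which none of the comparisons used. It held 6 control summits with a median pileup of 67 reads (range 64 to 73) and 7 overexpression summits with a median of 149 (126 to 160). Relative to each library's genome average the local density was 24.5-fold in control and 56.5-fold in the overexpression library, a ratio of 2.31.

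The overexpression library had more summits at gene ends. The tables argue against depth as the cause, since the overexpression library had 0.893 of the control depth. Whether a higher control background hid equal pileups cannot be decided. At paired summits the log2 pileup ratio was 0.27 higher at gene ends than far from genes. The local background ratio was higher there too, by 0.17. These pairs were called in both libraries, so places where control background hid a peak are not among them. Broader coverage of gene-dense regions as the whole cause would have raised the share of summits 2000 to 5000 bp away by at least 1.7 times, and the ratio was 1.1. That test cannot decide, because local background in 10 kb windows includes reads of gene-end peaks and can hide summits at that distance. At 3500 to 4000 bp summits stood at 0.977 (control) and 1.009 (overexpression) times the random level. At 6000 to 6500 bp they stood at 1.235 and 1.232 times. The 0.17 shows that local density over 10 kb, which includes the peaks' own reads, went up with the pileups. Better recovery of open or GC-rich DNA in that library cannot be told apart from more TCF19 at gene ends, and no sequence was used here. Genes of other cell types gained 9.8 percentage points less than the other lists but still gained 7.4. All protein-coding genes gained 10.1. The 7.4 rests mostly on muscle, which gained 6 genes. Epidermis and testis gained 2, liver 1, and neuron, blood and olfactory receptors 0. The 25 olfactory receptor genes had no peak in either library, which lowered the joint gain. At low local background the order turned, with 8.2 points at genes of other cell types and 2.3 at the other lists. Better recovery and more TCF19 at gene ends both stay open as hypotheses. With 1 library per group, a difference between preparations is untested.

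The overexpression library had 3 summits over TCF19. An artefact of alignment that affects every library is argued against by 0 summits there in control. Reads from integrated copies of the lentivirus, which would align to TCF19 itself, cannot be told apart from binding of TCF19 to its own gene. The local density of 423 reads per 10 kb includes the reads of the summits themselves (258 summed over the 3). Taking summit pileups, a lower bound of a peak's reads, out of both leaves 165 at TCF19 and a median of 101 in the flanks (35.8 to 173), a ratio of 1.63, which decides nothing, and neither the exons nor the sequence of the vector was used here.

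The summits of highest fold lay far from genes in both libraries. Of the 100 highest of the overexpression library, 99% overlapped a control interval and 8 lay at gene ends, against 15.57% of all its summits. This is consistent with reads piling up on repeated or misassembled sequence in both libraries, but binding at the same places would overlap as well. The pileups were not level: at the highest summit they were 87 reads in control and 155 in the overexpression library. No biological explanation was tested, and repeat content was not measured.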

How the results depend on the processing

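Alternatives on local background, on depth, on intervals seen in 1 list alone, on gene length and on moved intervals were chosen only after the data were seen. With 1 library per group no library could be left out, and no result has a replicate check. No paired analysis was possible because each group has 1 library. Not run, for want of a genome sequence, were the repeat filter on overlap, random lists matched on promoter GC and start sites, and the sequence at summits. The order of the libraries turned in some gene lists, given last. The gene-end share of the overexpression library over that of control, 1.9 as reported, was 1.59 to 2.57 under the settings planned before the data were examined, 1.86 at low local background (at most 3 times the genome average) and 4.98 over summits whose interval was in 1 list alone. TCF19 had 0 control and 3 overexpression summits at a q-value below 0.01 too. The values below moved beyond counting error, or by over 1.5 times for counts, because fewer peaks, wider windows or other peaks enter; causes beyond that were not tested.

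At a q-value below 1e-05 there were 39920 control and 35561 overexpression summits. Control overlap (43.01% as reported) was 33.26% at 50% of both peaks, 23.9% with summits within 100 bp, 41.93% at q below 0.01, 33.4% at q below 1e-05, 22.86%, 21.57% and 25.1% with 1000, 5000 and 10000 summits of highest fold from each list, 41.57% at low local background and 63.84% where the other library had the depth. Overexpression overlap (67.36%) was 52.42%, 37.46%, 64.01%, 38.56%, 22.77%, 21.52%, 25.05%, 69.49% and 75.93% in the same order. Equal numbers of peaks make the lists equally long, so the percentages must then be nearly level. That level says nothing about the libraries.

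The control gene-end share (8.21%) was 5.45% within 500 bp, 11.3% within 2000 bp, 14.85% for all annotated genes, 8.37% at q below 0.01, 6% and 5.94% for the 1000 and 5000 summits of highest fold, 7.64% at low local background and 2.92% of summits not in the other list. The overexpression share (15.57%) was 11.21%, 19.56%, 23.64%, 16.28%, 13.7%, 14.88%, 14.21% and 14.51% in the same order, and 20.78% at q below 1e-05.

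Genes with a summit in both libraries (9742) were 2197 at q below 1e-05, where neither library had one at 12118 (5872 as reported). With equal numbers of summits of highest fold they were 6302, with 6633 in the overexpression library alone (3193) and 575 in control alone (1167). Lists above the 95th percentile in control (2) were 1 at q below 0.01 and 1 at low local background, where those in the overexpression library were 2 (6 as reported). With random lists matched on gene length they were 9 in the overexpression library, with ribosomal proteins and histones among those added. Chance overlap was 4.24% for control and 6.68% for overexpression with moved intervals, against 3.23% and 5.1% at random.

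Of the 23 lists, the overexpression count less the control count turned from positive to negative in 5 at low local background. It was -2 genes for MAPK (5 as reported) and Wnt (1), and -1 for chromatin regulators (4) and epithelial genes (1). No list turned within 2000 bp or at q below 0.01. The gain at lists other than those of other cell types (17.2 percentage points) was 2.3 at low local background, where its excess over that of other cell types (9.8) was -5.9. These changes decide neither for nor against the reported differences, because the limit acts on a local background that includes the peaks' own reads and removed 23.1% of gene-end summits in the overexpression library and 15.8% in control.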

Other observations

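The gene families in this part were chosen after the data were seen, and no test of the condition was run on them. Several families of subunits and factors had more gene-end peaks in the overexpression library than in control. Proteasome subunits (PSM) had a peak at 86.0% of 50 genes against 54.0% in control. Translation initiation factors (EIF) had 90.9% of 55 against 63.6%, respiratory complex I subunits (NDUF) 82.6% of 46 against 56.5%, and cytochrome c oxidase subunits (COX) 76.9% of 26 against 42.3%. All ribosomal protein genes (RPL and RPS) had 72.6% of 95 against 50.5%. At low local background (at most 3 times the genome average), a limit that removed more gene-end summits in the overexpression library, the gains were smaller, 26.0 percentage points for PSM, 23.1 for COX, 18.2 for EIF, 12.6 for RPL and RPS and 8.7 for NDUF. Within 2000 bp of gene ends they were 16.0 for PSM (32.0 within 1000 bp), 16.4 for EIF (27.3), 16.8 for RPL and RPS (22.1), 19.6 for NDUF (26.1) and 23.1 for COX (34.6). The other families looked at were mitochondrial ribosomal proteins (68.8% against 50.6%), RAB GTPases (83.8% against 68.9%), kinesins (76.9% against 64.1%), HOX genes (57.5% against 42.5%) and zinc finger genes (74.1% against 62.9%). Their gains ran from 11.2 points (zinc finger genes) to 18.2 (mitochondrial ribosomal proteins). Over all protein-coding genes the shares were 64.8% and 54.6%, a gain of 10.1 points. At low local background kinesins had 64.1% against 61.5% and HOX genes 12.5% against 10%.

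Some other families, picked by the same look at the data, had fewer gene-end peaks in the overexpression library than in control. Away from the ends of protein-coding genes the overexpression list was shorter too, with 94201 summits against 155620 in control. The drops in this paragraph were not corrected for that. Olfactory receptors had a peak at 5.4% of 392 genes against 11.5%, MAGE genes at 28.6% of 35 against 48.6%, chemokines at 31.0% of 42 against 47.6%, and beta-defensins at 7.7% of 39 against 17.9%. Cytochrome P450 genes had 50.0% of 56 against 60.7%, keratin-associated proteins 57.4% of 94 against 60.6% (55.3% in both at a q-value below 0.01), and bitter taste receptors 4.0% of 25 against 8.0%. The cytochrome P450 difference was smaller at low local background (42.9% against 46.4%) and within 2000 bp (64.3% against 71.4%), and that of MAGE genes at a q-value below 0.01 (28.6% against 40%). Protocadherins had 36.9% of 65 in both libraries within 1000 bp, but 80% against 73.8% within 2000 bp and 23.1% against 29.2% at low local background. Several of these families hold near-identical copies, so the place of single peaks is uncertain. Immunoglobulin and T cell receptor V segments had 15.3% of 248 against 29.4%, and pseudogenes 19.9% of 15212 against 26.5%. Transfer RNA genes went the other way, with 35.0% of 429 against 26.8%, and long noncoding RNA genes had 32.1% of 18177 against 34.1%. These counts come from lists of 169542 control and 111569 overexpression summits on chromosomes 1 to 22 and X.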
